A study of Homo sapiens with 34 samples.

How the data were processed

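RNA was sequenced from NK-92MI cells, a human natural killer cell line that makes its own IL-2, after 24 h in a water extract or in phosphate-buffered saline (PBS, the vehicle). The extracts were Bojungikki-tang (BJIKT, a herbal formula), 4 of its ingredients (ginseng, Astragalus, Atractylodes and Glycyrrhiza) and a mixture of those 4. BJIKT and each ingredient were used at 500 and at 125 µg/mL, and the mixture held 125 µg/mL of each ingredient. The 34 libraries fell into 12 groups, of which 10 had 3 libraries and 2, BJIKT at 125 and ginseng at 500, had 2 libraries. Groups are named by extract and concentration, for example Glycyrrhiza_500. Per the labels, 500 ng of total RNA with an integrity number above 7 went into each strand-specific library, read as paired ends of 100 bp. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

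The authors deposited 1 table of RSEM expected counts (estimated read pairs per gene, not normalized) for 60675 Ensembl gene identifiers. The submitters' processing notes name FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3 with the builds hg38 and GRCh38. The annotation release and the strand setting are not given in the sources used here. Expected counts were rounded to whole numbers, since 90.8% of the values were whole already. Gene symbols came from a human gene name table, which matched 93.2% of the identifiers, and coordinates (GRCh38) and transcript lengths from GENCODE release 29, which held 94.0% of them. Totals per library ran from 28.5 to 35.6 M read pairs, with a median of 31.0 M.

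The description fields number the libraries in 3 sets. Set 1 holds vehicle, BJIKT at both concentrations and ginseng_500 (10 libraries). Set 2 holds ginseng_125, Astragalus at both concentrations and Atractylodes_500 (12 libraries). Set 3 holds Atractylodes_125, Glycyrrhiza at both concentrations and the mixture (12 libraries). The labels do not say what the sets are. Because vehicle is in set 1 alone, set and treatment cannot be separated in the comparisons of sets 2 and 3 with vehicle, so comparisons within a set stand beside them.

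Before the data were examined, the groups, the comparisons, the tests, the named-gene rule, 38 gene lists and the alternatives were fixed. Later additions are named as such. Genes were kept by edgeR's filterByExpr with the 12 groups, which left 16212 genes. edgeR 4.0.16 with TMM factors fitted 1 quasi-likelihood model of all 34 libraries, and each comparison was an F test of a contrast, with Benjamini-Hochberg adjustment within the comparison and a threshold of 0.05. The common dispersion corresponded to a biological coefficient of variation of 10.57%. There were 23 comparisons: 11 treatments with vehicle, 5 between concentrations, 5 between treatments, the mixture against the sum of its 4 parts, and a joint test of any difference among the 4 ingredients at 500. Fold changes are log2 with the standard error (SE) that the F statistic implies. Levels are CPM (counts scaled by library size) with the SD over the libraries of a group.

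In each comparison the rule named the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold, with a mean of at least 5 CPM no overlap between the libraries of both groups, and a symbol that is not a clone or locus name. It named 4 and 4 where no 500 group or mixture met vehicle. It also named up to 4 members of each list with the smallest adjusted p, and 30 genes of natural killer function, stress and metabolism always. The text gives a part of these, picked after their values had been seen, and 1 gene is not reported here. A gene named in 1 comparison may be followed in others.

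The lists cover natural killer effectors and receptors, cytokines, signalling targets, stress responses, metabolism, cell cycle, ribosomes, transcription factors and markers of other cell types. Lists with at least 3 tested members, 36 of the 38, were compared with all other genes by camera of limma 3.58.1 with its preset correlation of 0.01, adjusted over the lists within a comparison. Each was run again with the correlation estimated from the data. Also fixed beforehand was fry of limma, a rotation test of a list without the other genes. Its values are given below only for lists of ginseng_500 and BJIKT_125 against vehicle. Of the 106 calls over the 11 comparisons with vehicle, 19 held with an estimated correlation, and every list result below states which. The erythroid and platelet list had 0 tested members and the epithelial and fibroblast list 1. Genes are not independent replicates, so correlations across genes were set against rearrangements of the libraries.

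The recovery of known changes was tested on simulated data with the dispersions of these libraries. Genes were drawn independently, each with the same dispersion in every group. Deviations of a whole library, as some real libraries had, were therefore absent, and the recovery does not cover them. With 3 libraries per group, edgeR recovered 95 of 100 genes changed 2-fold and 68 of 100 changed 1.5-fold, with 13 unchanged genes called among 15758 run. With 2 libraries against 3 it recovered 96 and 74, with 6 unchanged genes called. DESeq2 recovered 96 and 72, and 95 and 80, with 27 and 16 unchanged genes called.

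The alternatives fixed beforehand were RLE in place of TMM factors, no filter on low counts, DESeq2 1.42.0, a fit of the compared groups alone, the replicate number of the titles as a block, and leaving out each library in turn. For the correlations they were other prior counts than 2, a CPM minimum of 10 and leaving out the 1% of genes with the largest changes. Replicates that share a number tended to deviate together in 2 comparisons: ginseng_125 with vehicle and the mixture with Atractylodes_125, where all 3 same-number pairs correlated above 0.1. Replicates within a group differed beyond sampling noise, with a chi-square per degree of freedom from 3.0 to 184.3, so no library was counted as a copy of another and the number of libraries, more than their depth, set the precision.

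A further 2 alternatives were added after seeing the data. In 5 libraries the genes deviated from the median library with an SD above 0.2 on the log2 scale, over 8116 genes with a mean log2 CPM above 4, and the other libraries stayed at or below 0.153. These 5 are Astragalus_500 replicates 1 and 3, Atractylodes_500 replicate 3, Glycyrrhiza_125 replicate 2 and BJIKT_500 replicate 1, called the 5 atypical libraries below. All comparisons were repeated without them, with the filter applied anew, and with a smooth trend of each library's deviations over transcript length and GC content (mgcv 1.9.3) as an offset. The threshold of 0.2 was set after the deviations had been seen. No library was left out of the values reported unless the text says so.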

Results

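The transcriptomes of 34 libraries of NK-92MI cells were compared after 24 h in an extract or in PBS. Vehicle, BJIKT_500, ginseng_125, the mixture and both concentrations of Astragalus, Atractylodes and Glycyrrhiza had 3 libraries each, and BJIKT_125 and ginseng_500 had 2 each. Messages of granule proteins of natural killer cells were abundant: GZMB, the gene of the granule protease granzyme B, stood at 2263 ± 93.35 CPM (SD, n = 3) in vehicle and GNLY, the gene of the pore-forming granulysin, at 674.2 ± 13.01 CPM (SD, n = 3). The B cell, myeloid and T cell lists had 3, 5 and 6 tested members, and the T cell list shares genes with natural killer cells. In Glycyrrhiza_500 against vehicle 1 myeloid gene rose and 1 T cell gene fell, and both lists missed the threshold there (adjusted p = 0.198 and 0.91). The first principal component of log2 CPM held 19.86% of the variance and the second 9.139%. In 5 libraries, named above as atypical, genes deviated widely from the median library, in 4 of them along transcript length and in BJIKT_500 replicate 1 along GC content (Spearman's rho 0.74 across genes, which are not independent replicates).

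**Figure D1:**
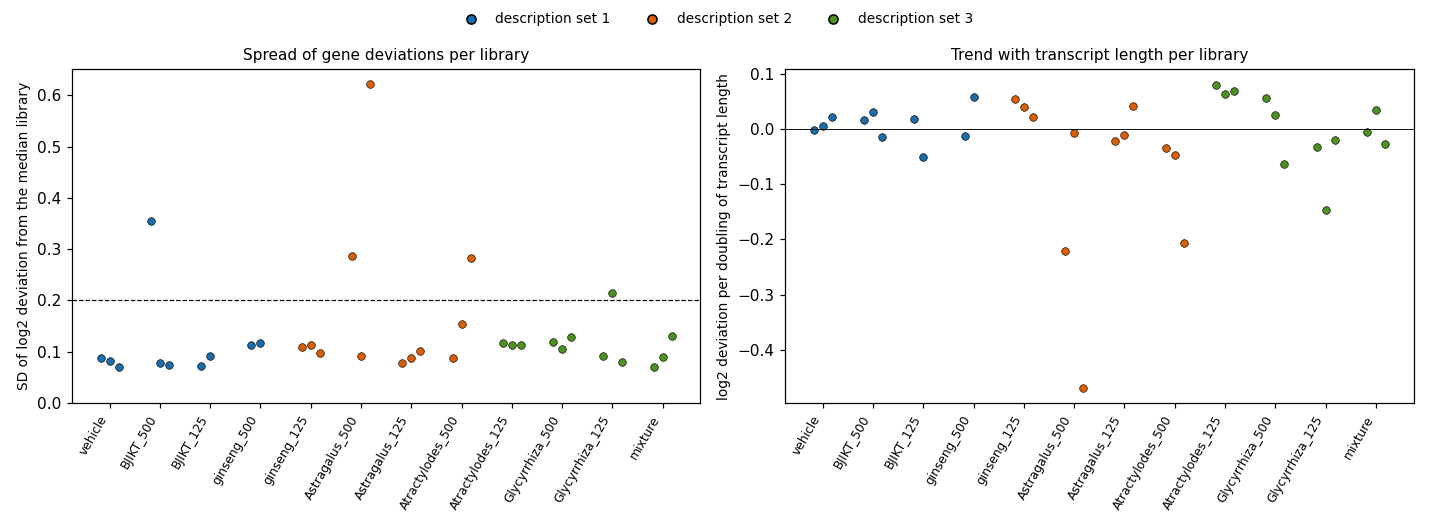
Each point is 1 of the 34 libraries, coloured by description set: the SD over genes of its log2 deviation from the median library, with a dashed line at 0.2, and the slope of that deviation per doubling of transcript length. Astragalus_500 replicate 3 lies highest at 0.623, and its slope is -0.469.

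What Glycyrrhiza did at 500 µg/mL was asked by comparing it with vehicle. Transcripts of IGF1, the gene of insulin-like growth factor 1, fell from 234.8 ± 2.687 to 107.1 ± 3.876 CPM (SD, n = 3 each). IGF1 (ENSG00000017427) lies on chromosome 12 at 102395874 to 102481744 of GRCh38, and MPZL3 (ENSG00000160588) on chromosome 11 at 118226690 to 118252350. Messages of MPZL3, an immunoglobulin-like membrane protein, fell from 97.94 ± 2.823 to 48.64 ± 0.717 CPM (SD, n = 3 each). ASB2, part of a ubiquitin ligase, fell from 150.3 ± 1.926 to 81.72 ± 3.565 CPM (SD, n = 3 each), and CXCL8, the gene of the neutrophil-attracting chemokine interleukin-8, from 16.73 ± 4.163 to 4.186 ± 1.25 CPM (SD, n = 3 each). These genes (ENSG00000100628 and ENSG00000169429) lie on chromosome 14 at 93934153 to 93976791 and on chromosome 4 at 73740506 to 73743716. In the other direction CADM1, an adhesion molecule that natural killer receptors bind on other cells, rose from 8.797 ± 0.334 to 15.22 ± 0.63 CPM, and PSAT1, an enzyme of serine synthesis, from 16.99 ± 0.788 to 24.04 ± 1.395 CPM (SD, n = 3 each). By edgeR 224 genes passed, of which 68 rose and 156 fell, 78 of them by at least 1.5-fold and 24 by at least 2-fold. Each gene named for this comparison as past the threshold had all 3 Glycyrrhiza_500 libraries on 1 side of all 3 vehicle libraries, which the naming rule required of the largest changes.

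Genes that fell included CXCL8 (log2 change -2.0 ± 0.29 SE, adjusted p = 0.000102), RGS1, a brake on G protein signals (-1.51 ± 0.26, 0.00115), the heat shock chaperone gene HSPA1B (-1.38 ± 0.21, 0.000167) and IGF1 (-1.13 ± 0.09, 4.73e-09). PFKFB4, a regulator of glycolysis (-1.13), PPP1R15A, which ends the stress block on translation (-1.11), EGR2 (-1.07) and MPZL3 (-1.01) fell too. CXCL8, RGS1, HSPA1B and PFKFB4 were also lower in ginseng_500 than in ginseng_125, among 31 genes that rose and fell together within other groups. Of those 31, 18 fell here, so variation between libraries not tied to treatment stays open for them. Genes that rose included KLF2, a transcription factor of lymphocyte quiescence and homing (0.80 ± 0.14, adjusted p = 0.000991), CADM1 (0.79 ± 0.11, 0.000116), SLAMF8 (0.58), SLC7A11, the cystine transporter (0.57), CCR2, a chemokine receptor (0.56), PSAT1 (0.50), APOL4 (0.49) and CD160 (0.47). SLC7A11 lost the call without vehicle replicates 1 or 2 and without Glycyrrhiza_500 replicates 1 or 2 (adjusted p up to 0.0866).

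Of 21 tested NF-kB targets 0 rose and 6 fell, 8 adjusted over the list alone, with a median log2 change of -0.247 (camera adjusted p = 8.34e-13; adjusted p = 1.02e-05 with an estimated correlation). Among them were BIRC3, an inhibitor of cell death (-0.60 ± 0.07, adjusted p = 1.81e-06), the feedback inhibitors NFKBIA (-0.43) and TNFAIP3 (-0.78), and NFKB2 (-0.54). Immediate early genes followed: 1 of 25 rose and 8 fell, or 2 and 12 adjusted over the list alone (median -0.188, adjusted p = 1.9e-10; 0.0121 with an estimated correlation), with FOSB at -0.96 ± 0.12. Of 14 hypoxia response genes 4 fell, 6 adjusted over the list alone (median -0.32, adjusted p = 1.9e-14; 0.00857 with an estimated correlation), including MXI1 (-0.71 ± 0.09), KDM3A (-0.62 ± 0.13) and PDK1 (-0.57 ± 0.14). Without 1 library at a time, PDK1 lost the call in 5 of 6 fits, all but that without vehicle replicate 3 (adjusted p up to 0.257). KDM3A lost it without vehicle replicate 2 and without Glycyrrhiza_500 replicate 2 (up to 0.0856). Of 8 glucocorticoid targets 2 fell, 3 adjusted over the list alone, among them TSC22D3 (-0.63 ± 0.12; list adjusted p = 9.7e-05 and 0.00238 with an estimated correlation). Of 43 replication-dependent histone genes 1 fell, 2 adjusted over the list alone (median -0.302, list adjusted p = 4.45e-09 and 0.00161 with an estimated correlation). The median level of these histone genes was 0.933 CPM, so many lay near the floor and their log2 changes are imprecise. Of 4 tested aryl hydrocarbon receptor targets 1 fell, 1 adjusted over the list alone (list adjusted p = 0.000935, and 0.00857 with an estimated correlation). The 1 that fell was ASB2 (-0.88), while AHRR, TIPARP and NQO1 did not pass. CYP1A1 and CYP1B1 of this list were not tested, with at most 3 counts in a library.

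Lists whose call ended with an estimated correlation included ATF4 and amino acid response genes, of which 3 of 26 rose and 2 fell, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.000719; adjusted p = 0.0711 with an estimated correlation). PSAT1 and AARS1, an alanyl-tRNA synthetase (0.29 ± 0.06), rose, AARS1 not with no filter (0.199). Of 23 NRF2 targets 3 rose, 4 adjusted over the list alone, including GCLM of glutathione synthesis (0.36 ± 0.07) and SRXN1 (0.21 ± 0.05); the list had an adjusted p = 0.00225, and adjusted p = 0.142 with an estimated correlation. SRXN1 lost the call with no filter, with the compared groups alone and in 5 of the 6 fits without 1 library, all but that without vehicle replicate 1 (adjusted p up to 0.895). HERPUD1 (0.38 ± 0.06) was the 1 of 21 unfolded protein response genes that rose, 1 adjusted over the list alone (adjusted p = 0.0191; adjusted p = 0.142 with an estimated correlation). Of 19 heat shock genes 2 fell, 2 adjusted over the list alone, among them DNAJB1 (-0.78 ± 0.14), with list adjusted p = 0.00814 and adjusted p = 0.142 with an estimated correlation. Among 46 interferon-stimulated genes 0 passed over all genes, while 1 rose and 5 fell adjusted over the list alone (adjusted p = 0.000296; adjusted p = 0.109 with an estimated correlation).

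Among genes of natural killer function, 1 of 20 activating receptor and adaptor genes rose and 3 fell, or 2 and 6 adjusted over the list alone (adjusted p = 0.0336; adjusted p = 0.142 with an estimated correlation). CD226, an activating receptor, fell from 25.98 ± 1.283 to 16.0 ± 0.619 CPM (SD, n = 3 each), NCR2 changed by -0.44 ± 0.08 and SLAMF7 by -0.32 ± 0.05. CD96, a receptor that shares ligands with CD226, fell by 0.40 on the log2 scale and KLRD1, the CD94 chain of several receptors, rose by 0.35. The death receptor gene FAS fell by 0.35 and IL2RA, a chain of the IL-2 receptor, by 0.28. With no filter SLAMF7, KLRD1 and IL2RA lost the call (adjusted p up to 0.215), and KLRD1 also lost it without vehicle replicates 1 or 2 and without Glycyrrhiza_500 replicates 2 or 3. Of 17 cytotoxic effector genes 0 passed by edgeR, over all genes or adjusted over the list alone. Among them GZMB had -0.14 ± 0.12, PRF1, the perforin gene, 0.01 ± 0.09 and GNLY 0.04 ± 0.17 (SE, adjusted p from 0.86 to 0.998). IFNG, of the cytokine list, had -0.11 ± 0.10 (SE, adjusted p = 0.893). Of 23 cytokine and chemokine genes 1 rose, TNFSF4 (0.64 ± 0.16), and 1 fell, or 2 and 9 adjusted over the list alone (adjusted p = 9.15e-05; adjusted p = 0.142 with an estimated correlation). TNFSF4 lost the call with no filter and in all 6 fits without 1 library (up to 0.215). Of 20 IL-2 and STAT5 targets 3 rose and 2 fell, or 5 and 5 adjusted over the list alone (list adjusted p = 0.91), with PIM2, a survival kinase, at 0.45 ± 0.07. Of 23 p53 targets 0 rose and 3 fell, or 2 and 3 adjusted over the list alone (0.325), and of 29 lymphocyte transcription factors 1 fell, or 2 rose and 1 fell adjusted over the list alone (0.231). Of 30 genes of G2/M and mitosis 0 passed by either adjustment (list adjusted p = 0.0471; adjusted p = 0.186 with an estimated correlation). The count of 224 was 141 without vehicle replicate 1, 134 without vehicle replicate 2, 136 without Glycyrrhiza_500 replicate 2 and 149 without replicate 3, and 1174 without the 5 atypical libraries, none of which is in this comparison. Vehicle and Glycyrrhiza_500 lie in different description sets.

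**Figure D2:**
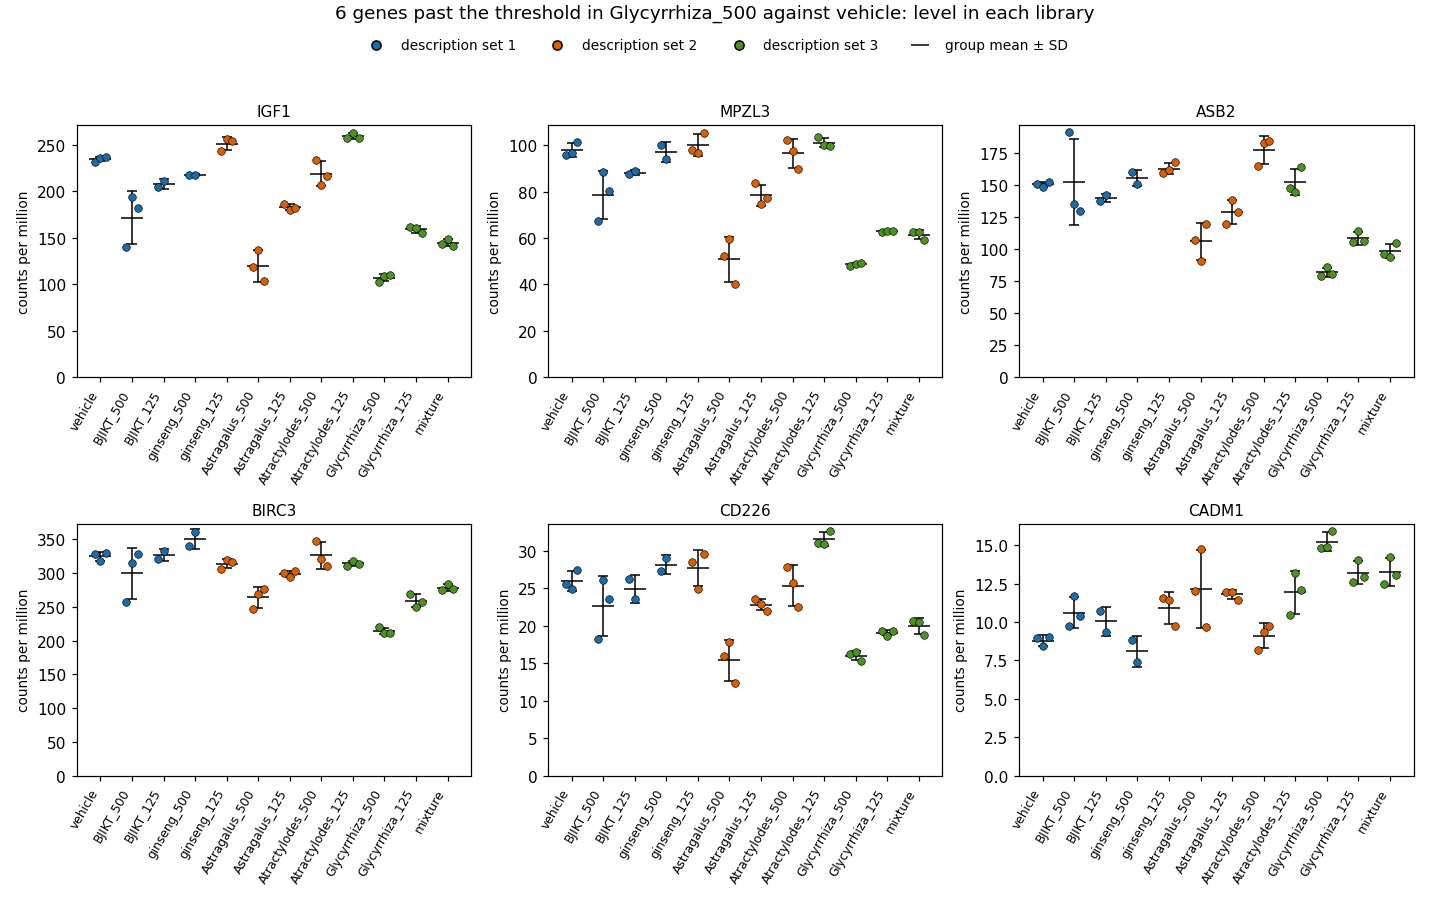
CPM of IGF1, MPZL3, ASB2, BIRC3, CD226 and CADM1 in each library (points, coloured by description set), with the mean and SD of each of the 12 groups. IGF1 stands at 107.1 in Glycyrrhiza_500, 158.9 in Glycyrrhiza_125 and 144.6 in the mixture against 234.8 in vehicle.

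Glycyrrhiza at 125 µg/mL was compared with vehicle next. MPZL3 fell from 97.94 ± 2.823 to 62.94 ± 0.241 CPM (SD, n = 3 each; log2 change -0.64 ± 0.09 SE, adjusted p = 0.00183). LACC1 (-0.65 ± 0.12, adjusted p = 0.0141), TCAF2 (-0.60), PPP1R15A (-0.57), MXI1 (-0.47), BIRC3 (-0.33) and CD96 (-0.23) also fell. CADM1 rose by 0.59 ± 0.12, CD160 by 0.40 ± 0.08 and HERPUD1 by 0.31 ± 0.06 (SE, adjusted p = 0.0262 for each). In all, 21 genes passed by edgeR, 3 of which rose and 18 fell. Of the 14 hypoxia response genes 1 fell, 4 adjusted over the list alone (adjusted p = 2.41e-07; adjusted p = 0.103 with an estimated correlation), and of the 21 NF-kB targets 1 fell, 2 adjusted over the list alone (adjusted p = 0.00135; adjusted p = 0.0504 with an estimated correlation). The count was 9, 6 and 4 without vehicle replicates 1, 2 and 3, 4, 5 and 7 without Glycyrrhiza_125 replicates 1, 2 and 3, and 154 without the 5 atypical libraries, of which Glycyrrhiza_125 replicate 2 is 1. MPZL3 was the 1 gene named here that passed under each alternative, and TCAF2 lost the call in 4 and the others in all 6 of the fits without 1 library.

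Between the Glycyrrhiza concentrations, which lie in 1 description set, IGF1 was lower at 500 than at 125 (log2 difference -0.57 ± 0.09 SE, adjusted p = 0.00604). FOSB (-0.65 ± 0.12, adjusted p = 0.0441), HIC1, a transcriptional repressor (-0.53, 0.0483), and FUCA1, a lysosomal fucosidase (-0.42, 0.0384), were also lower, among 6 genes past the threshold by edgeR, 0 of them higher. NF-kB targets were lower as a list (median -0.131, adjusted p = 0.00217 with an estimated correlation), with 0 past over all genes and 3 adjusted over the list alone. The count was 0, 1 and 1 without Glycyrrhiza_500 replicates 1, 2 and 3, 0, 0 and 2 without Glycyrrhiza_125 replicates 1, 2 and 3, 1 with the replicate number as a block and 37 without the 5 atypical libraries. DESeq2 gave 35. IGF1 lost the call without Glycyrrhiza_500 replicate 1 and without Glycyrrhiza_125 replicates 1 or 2. FOSB, HIC1 and FUCA1 lost it with the block, with the compared groups alone and in the fits without 1 library, except FUCA1 without Glycyrrhiza_125 replicate 3.

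The mixture of 4 ingredients was compared with vehicle to ask what they do together. IGF1 fell from 234.8 ± 2.687 to 144.6 ± 3.825 CPM and MPZL3 from 97.94 ± 2.823 to 61.53 ± 1.897 CPM (SD, n = 3 each), both also called under each alternative (log2 changes -0.70 ± 0.08 and -0.67 ± 0.09 SE, adjusted p = 0.000139 and 0.000503). ASB2 (-0.61 ± 0.10, adjusted p = 0.00637), PPP1R15A (-0.61), TSC22D3 (-0.58), LACC1 (-0.57), FOSB (-0.57), TCAF2 (-0.54), MXI1 (-0.47), the antiproliferative gene BTG2 (-0.36) and CD96 (-0.23) fell as well. CADM1 (0.59 ± 0.12, adjusted p = 0.0153), SLAMF8 (0.46), ATP8A2 (0.36), CD86, a costimulatory ligand (0.34), APOL4 (0.31), PMS1 (0.29), PDE7A (0.29) and SOCS2, an inhibitor of cytokine signals (0.24), rose. By edgeR 52 genes passed, 9 up and 43 down, 16 of them by at least 1.5-fold. ASB2 lost the call without mixture replicate 2, and the genes named here other than ASB2, IGF1 and MPZL3 lost it in at least 3 of the 6 fits without 1 library. With no filter APOL4, ATP8A2, CD86, CD96, PDE7A, PMS1 and SOCS2 lost it, and ATP8A2 with the compared groups alone.

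Of the 25 immediate early genes 0 rose and 2 fell in the mixture, or 1 and 9 adjusted over the list alone (median -0.155, adjusted p = 4.01e-06; adjusted p = 0.0814 with an estimated correlation). Of the 14 hypoxia response genes 1 fell, 5 adjusted over the list alone (median -0.277, adjusted p = 2.15e-09; adjusted p = 0.0541 with an estimated correlation). Glucocorticoid targets (1 of 8 fell, 2 adjusted over the list alone; adjusted p = 0.0401 with an estimated correlation) stayed past. GZMB (0.04), PRF1 (0.02) and IFNG (0.02) had adjusted p = 1. The count of 52 was 22, 15 and 10 without vehicle replicates 1, 2 and 3, 16, 9 and 8 without mixture replicates 1, 2 and 3, and 577 without the 5 atypical libraries, none of which is in this comparison.

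Against Atractylodes_125, a group of the same description set, the mixture had lower FGFBP2, a secreted product of cytotoxic lymphocytes, at 19.57 ± 1.135 against 35.5 ± 1.27 CPM (SD, n = 3 each; log2 difference -0.86 ± 0.13 SE, adjusted p = 0.000672). IGF1 (-0.84 ± 0.09, adjusted p = 3.26e-06), MPZL3 (-0.72 ± 0.09, 0.000115), CD226 (-0.66 ± 0.11, 0.00191) and ASB2 (-0.63 ± 0.10, 0.00193) were lower too, and these 5 passed under each alternative. RANBP3L (-0.81), TSC22D3 (-0.65), BTG2 (-0.35), SLAMF7 (-0.29) and CD96 (-0.28) were lower, and PSAT1 (0.37), TMEM98 (0.33), CD86 (0.30) and SOCS2 (0.27) higher. In all, 55 genes passed by edgeR, 4 higher and 51 lower, and 54 with the replicate number as a block. Of the 51, 45 also fell in Glycyrrhiza_500 against vehicle, a comparison that shares no library with this 1, where independent lists would share 0.49. Ribosome biogenesis genes were higher as a list (median 0.112, adjusted p = 1.18e-07; 0.00731 with an estimated correlation), with 0 of 26 past over all genes and 1 adjusted over the list alone. The count was 28, 26 and 30 without Atractylodes_125 replicates 1, 2 and 3, 26, 27 and 23 without mixture replicates 1, 2 and 3, and 717 without the 5 atypical libraries. SLAMF7, CD96, BTG2, PSAT1, TMEM98, CD86 and SOCS2 lost the call with no filter. PSAT1, TMEM98 and CD86 lost it in all 6 fits without 1 library, RANBP3L, BTG2 and SOCS2 in 4 and TSC22D3 in 3.

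Between the mixture and BJIKT_500, which share a total concentration but not a description set, AGRN, the gene of the matrix protein agrin, was lower in the mixture (-0.84 ± 0.14 SE, adjusted p = 0.00776), as were PRSS53 (-0.67 ± 0.12), ASB2 (-0.63 ± 0.10), TCAF2 (-0.58 ± 0.11) and JUNB (-0.51 ± 0.10). CEBPZ (0.27, adjusted p = 0.00895), RIOK2, an assembly factor of the small ribosomal subunit (0.34), TARS1 (0.25) and SRSF6 (0.24) were higher. By edgeR 27 genes passed, 4 higher and 23 lower. Heat shock genes were higher (median 0.134, adjusted p = 0.0459 with an estimated correlation; 0 past over all genes and 6 adjusted over the list alone) and so were interferon-stimulated genes (median 0.131, 0.0427; 0 and 9), while NF-kB targets were lower (median -0.162, 0.0427; 0 and 5). The mean log2 CPM of NF-kB targets stood 0.167 above the vehicle mean in BJIKT_500 replicate 1, which is atypical. In BJIKT_500 replicates 2 and 3 it stood 0.005 and 0.008 above, so part of the NF-kB difference rests on 1 library. The count was 8, 308 and 643 without BJIKT_500 replicates 1, 2 and 3, 17, 1 and 3 without mixture replicates 1, 2 and 3, 0 with the compared groups alone and 193 without the 5 atypical libraries. Each of the 9 genes named here lost the call with the compared groups alone and without mixture replicate 2, each but ASB2 without mixture replicate 3, and each but AGRN and ASB2 without BJIKT_500 replicate 1. JUNB, RIOK2 and TARS1 lost it without mixture replicate 1, RIOK2 and TARS1 with the replicate number as a block, CEBPZ, PRSS53, RIOK2 and SRSF6 with length and GC offsets, and CEBPZ, RIOK2, SRSF6 and TARS1 with no filter.

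Against Glycyrrhiza_125, the mixture differed in 0 genes by edgeR (557 at an unadjusted p under 0.05) and in 2 by DESeq2. CCL4, a chemokine gene, had a log2 difference of -0.25 ± 0.12 SE (adjusted p = 0.992). Of the lists 7 passed, and 0 with an estimated correlation. Tested against the sum of the log2 changes of its 4 parts, the mixture departed in 0 genes by edgeR (314 at an unadjusted p under 0.05) and in 3 by DESeq2. Glycolysis genes had a median departure of -0.231 (camera adjusted p = 0.00778, and 0.626 with an estimated correlation). The contrast joins vehicle, the mixture and its 4 parts over 3 description sets, so it includes any difference between sets. It is less precise than a comparison of 2 groups, so a count of 0 does not show that the changes add up.

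In Astragalus_500, 5178 genes differed from vehicle by edgeR, and the 3 libraries differed from one another. RANBP3L (log2 change -1.12 ± 0.16 SE, adjusted p = 0.000102), SOS1, an activator of Ras (-1.11 ± 0.16, 0.000133), CEMIP2 (-1.10 ± 0.17, 0.000215), CD226 (-0.75 ± 0.11, 0.000122) and CD96 (-0.46 ± 0.05, 1.08e-06) fell. SOS1 was at 334.7 ± 6.537 CPM in vehicle and at 155.1 ± 62.41 in Astragalus_500 (SD, n = 3 each). ITGA1, an integrin (-0.77), RRM2B, a p53 target (-0.78), ASB2 (-0.51), BTG2 (-0.50), SLAMF7 (-0.38) and BIRC3 (-0.30) fell too, and OSM, the gene of oncostatin M (0.59 ± 0.11), rose. Without the 5 atypical libraries, which left replicate 2 alone of Astragalus_500 and assumed it to vary like the other groups, each of these passed again, for example RANBP3L at -0.67 (adjusted p = 0.00634), SOS1 at -0.63 (0.000211), CEMIP2 at -0.61 (2.71e-06), CD226 at -0.56 (0.00163), CD96 at -0.42 (1.82e-05), ASB2 at -0.74 (7.01e-06) and OSM at 0.40 (0.00822).

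Other large changes ended with the atypical libraries. CEBPD (1.07 ± 0.22 SE, adjusted p = 0.00358) had 0.31 without them (0.588), MKI67, a marker of dividing cells (-0.90 ± 0.17, 0.00177), had -0.41 (0.124), and CHCHD10 (1.05), NUDT8 (1.02), ALKBH7 (1.01), ZBED6 (-1.49 ± 0.41) and SRCAP (-1.10 ± 0.34) had adjusted p from 0.41 to 0.765, while HAGHL (0.98) still passed at 0.44 (0.0448). Of 17 cytotoxic effector genes 9 rose, 10 adjusted over the list alone (median 0.262, adjusted p = 0.00345; adjusted p = 0.576 with an estimated correlation and 0.771 without the atypical libraries). GNLY (0.68 ± 0.18, adjusted p = 0.0085) had 0.02 without them, GZMB (0.39 ± 0.12, 0.019) 0.00, IFNG (0.45 ± 0.10, 0.0056) 0.06 and NCR3, an activating receptor (0.40 ± 0.14, 0.0305), -0.15. Of 84 cytosolic ribosomal protein genes 58 rose, 66 adjusted over the list alone, of 83 nuclear-encoded respiratory chain genes 42, or 54, of 31 proteasome genes 21, and of 23 NRF2 targets 10 with 1 falling, or 12 with 1 (adjusted p = 0.576 with an estimated correlation for each of these lists). Their medians were 0.503, 0.468, 0.343 and 0.239, and without the atypical libraries -0.052, -0.059, -0.06 and 0.047, with 0 members past over all genes and list adjusted p from 0.168 to 0.358. Without Astragalus_500 replicate 3 ALKBH7, CHCHD10, ZBED6, SRCAP, GNLY, GZMB, IFNG and NCR3 lost the call. SRCAP also lost it without vehicle replicate 1 or Astragalus_500 replicate 1, GZMB without vehicle replicates 2 or 3 and NCR3 without vehicle replicates 1, 2 or 3. With length and GC offsets GZMB and IFNG lost the call as well. Of the 5178 genes, 2730 rose and 2448 fell. The count was 3422, 3117 and 2807 without vehicle replicates 1, 2 and 3, 3990, 8221 and 419 without Astragalus_500 replicates 1, 2 and 3, 0 with the compared groups alone and 143 without the 5 atypical libraries.

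Against Atractylodes_500, in the same description set, Astragalus_500 had lower MPZL3 (-0.93 ± 0.09 SE, adjusted p = 6.12e-07), RANBP3L (-1.24 ± 0.16, 2.56e-05), BMF, a death-promoting gene (-0.88 ± 0.10, 1.6e-06), ASB2 (-0.74), CD226 (-0.72) and CD96 (-0.40). All 6 also passed without the atypical libraries, which left 1 and 2 libraries. RRM2B (-0.76), ITGA1 (-0.59), FAS (-0.33) and SLAMF7 (-0.32) were lower as well. The chemokine genes XCL2 (0.85 ± 0.18, adjusted p = 0.0128), XCL1 (0.77 ± 0.17) and CCL4L2 (0.77 ± 0.13) were higher, and without the atypical libraries their adjusted p were 0.169, 0.0845 and 0.181. XCL1 and XCL2 also lost the call without Astragalus_500 replicate 3 and without Atractylodes_500 replicates 1 or 2. By edgeR 212 genes passed, 70 higher and 142 lower, and 80 of the 142 were also lower in Glycyrrhiza_500 than in vehicle, where independent lists would share 1.4. The ribosomal protein list, with 81 of 84 higher adjusted over the list alone, had adjusted p = 0.422 with an estimated correlation, and 0.842 without the atypical libraries. The count was 194, 5218 and 133 without Astragalus_500 replicates 1, 2 and 3, 102, 94 and 309 without Atractylodes_500 replicates 1, 2 and 3, and 0 with the compared groups alone.

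Between the Astragalus concentrations 4181 genes differed by edgeR, 2264 higher and 1917 lower at 500. ALKBH7 (1.00 ± 0.21 SE, adjusted p = 0.0164) was higher, RGPD2 (-0.95 ± 0.21, 0.0176) and MKI67 (-0.77 ± 0.17, 0.0176) were lower, and GNLY had 0.65 ± 0.18 (0.0195). Without the atypical libraries these had 0.31, -0.43, -0.29 and -0.01 (adjusted p from 0.804 to 0.999). All 4 also lost the call with the compared groups alone and without replicate 3 of Astragalus_500 or of Astragalus_125. The count was 3052, 7883 and 19 without Astragalus_500 replicates 1, 2 and 3, 2517, 1531 and 25 without Astragalus_125 replicates 1, 2 and 3, 0 with the compared groups alone and 23 without the 5 atypical libraries. Astragalus_125 differed from vehicle in 0 genes by edgeR (512 at an unadjusted p under 0.05) and in 4 by DESeq2. IGF1 stood at 182.8 ± 3.317 CPM and MPZL3 at 78.53 ± 4.512 CPM there (SD, n = 3), CD96 had -0.13 ± 0.05 and ASB2 -0.22 ± 0.10 (adjusted p = 1), and 0 lists passed.

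Atractylodes gave no gene past the threshold against vehicle by edgeR. At 500 the endoplasmic reticulum chaperones HSPA5 and HSP90B1 each had a log2 change of 0.19 (SE 0.05 and 0.06, adjusted p = 0.25), the hypoxia gene KDM3A -0.45 ± 0.13 (0.25), PFKFB4 -0.65 ± 0.20 (0.262) and IFNG 0.23 ± 0.10 (0.313), and GZMB had 0.06 and PRF1 0.07. The count was 0 (2376 at an unadjusted p under 0.05), with 39 by DESeq2, 1 without Atractylodes_500 replicate 3, which is atypical, and 719 without the 5 atypical libraries. Of 11 lists past, 0 held with an estimated correlation, among them hypoxia response genes (median -0.252, adjusted p = 8.98e-05; adjusted p = 0.376 with an estimated correlation; 0 past over all genes and 6 lower adjusted over the list alone). At 125 the count was 0 (577 at an unadjusted p under 0.05), 3 by DESeq2 and 810 with the compared groups alone. CCL4 had -0.45 ± 0.12 (adjusted p = 1), and IGF1 stood at 259.3 ± 3.312 CPM (SD, n = 3). Cytokine and chemokine genes had a median of -0.208 (adjusted p = 1.43e-05; adjusted p = 0.314 with an estimated correlation; 0 past over all genes and 3 lower adjusted over the list alone). Between the concentrations, in different sets, the count was 0 (3846 at an unadjusted p under 0.05), 105 by DESeq2, 1397 with the compared groups alone and 2248 without the 5 atypical libraries. Cholesterol synthesis genes FDPS (0.29 ± 0.09) and EBP (0.41 ± 0.13) had adjusted p = 0.151 there, and their list adjusted p = 0.494 with an estimated correlation, with 0 past over all genes and 5 higher adjusted over the list alone.

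In ginseng_500 against vehicle, RGS1 fell from 124.3 ± 35.2 (SD, n = 3) to 33.26 ± 11.19 CPM (SD, n = 2) and BNIP3L, a hypoxia-induced gene of mitophagy, from 51.22 ± 6.241 (SD, n = 3) to 28.97 ± 6.401 CPM (SD, n = 2). These were the 2 genes past the threshold by edgeR (log2 changes -1.90 ± 0.31 and -0.82 ± 0.14 SE, both adjusted p = 0.0245), and DESeq2 gave 22. Both lost the call without vehicle replicates 2 or 3 and without ginseng_500 replicate 2, RGS1 also without ginseng_500 replicate 1. Of the 14 hypoxia response genes 1 fell, 8 adjusted over the list alone (median -0.495, adjusted p = 5e-25; 0.00121 with an estimated correlation). Glycolysis genes (median -0.173, 0.00737 with an estimated correlation; 0 past over all genes and 6 lower adjusted over the list alone) and immediate early genes (median -0.116, 0.0365; 0 and 6) were lower as lists. Glucocorticoid targets were lower too (median -0.337, camera adjusted p = 0.000243 with an estimated correlation). Of these 8 genes, 0 passed over all genes and 4 adjusted over the list alone. Replication-dependent histone genes (median -0.182, camera adjusted p = 0.0365 with an estimated correlation) and genes of G2/M and mitosis (median -0.07, 0.0471) had 0 past by either adjustment. The histone genes had a median level of 0.933 CPM, so many lay near the floor. By fry, immediate early genes (adjusted p = 0.0661), histone genes (0.0521) and genes of G2/M and mitosis (0.0521) missed the threshold. The hypoxia response (0.0054), glycolysis (0.0141) and glucocorticoid (0.000841) lists passed by fry. The count was 6, 0 and 0 without vehicle replicates 1, 2 and 3, 1 and 0 without ginseng_500 replicates 1 and 2, 65 with the compared groups alone and 47 without the 5 atypical libraries. In ginseng_125 the count against vehicle was 0 by edgeR (438 at an unadjusted p under 0.05), 0 with the replicate number as a block, 2 by DESeq2 and 46 with the compared groups alone. BNIP3L had 0.25 ± 0.12 and NDRG1 0.27 ± 0.08 there (adjusted p = 1), and of 9 lists past 0 held with an estimated correlation.

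Between its concentrations, in different sets, ginseng at 500 had lower RGS1 (-2.08 ± 0.31 SE, adjusted p = 0.00173), RGS2 (-1.71 ± 0.33, 0.016), CXCL8 (-1.54 ± 0.32, 0.0287), HSPA1B (-1.52 ± 0.24, 0.00179) and BNIP3L (-1.07 ± 0.14, 0.000608). Among 14 hypoxia response genes 5 were lower, 12 adjusted over the list alone (median -0.647, 9.32e-05 with an estimated correlation), including PFKFB4 (-1.36) and P4HA1 (-0.85). Of 19 glycolysis genes 3 were lower, 8 adjusted over the list alone (0.000183 with an estimated correlation), with SLC2A3, a glucose transporter (-0.67), and PGK1 (-0.54). Of 25 immediate early genes 6 were lower, 7 adjusted over the list alone with 1 higher (0.00269 with an estimated correlation), among them EGR1 (-1.15), DUSP1 (-1.10), FOS (-1.06) and JUN (-0.92). DNAJB1 (-0.99) and TNFAIP3 (-0.83) were lower as well. By edgeR 31 genes passed, 0 higher and 31 lower, and DESeq2 gave 57. The count was 13 and 0 without ginseng_500 replicates 1 and 2, 39, 15 and 12 without ginseng_125 replicates 1, 2 and 3, and 168 without the 5 atypical libraries. RGS2, CXCL8, EGR1, SLC2A3 and TNFAIP3 also lost the call without ginseng_500 replicate 1 and without ginseng_125 replicates 2 or 3. FOS lost it without ginseng_500 replicate 1 or ginseng_125 replicate 3, PGK1 without ginseng_125 replicate 3 and TNFAIP3 with the replicate number as a block.

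**Figure D3:**
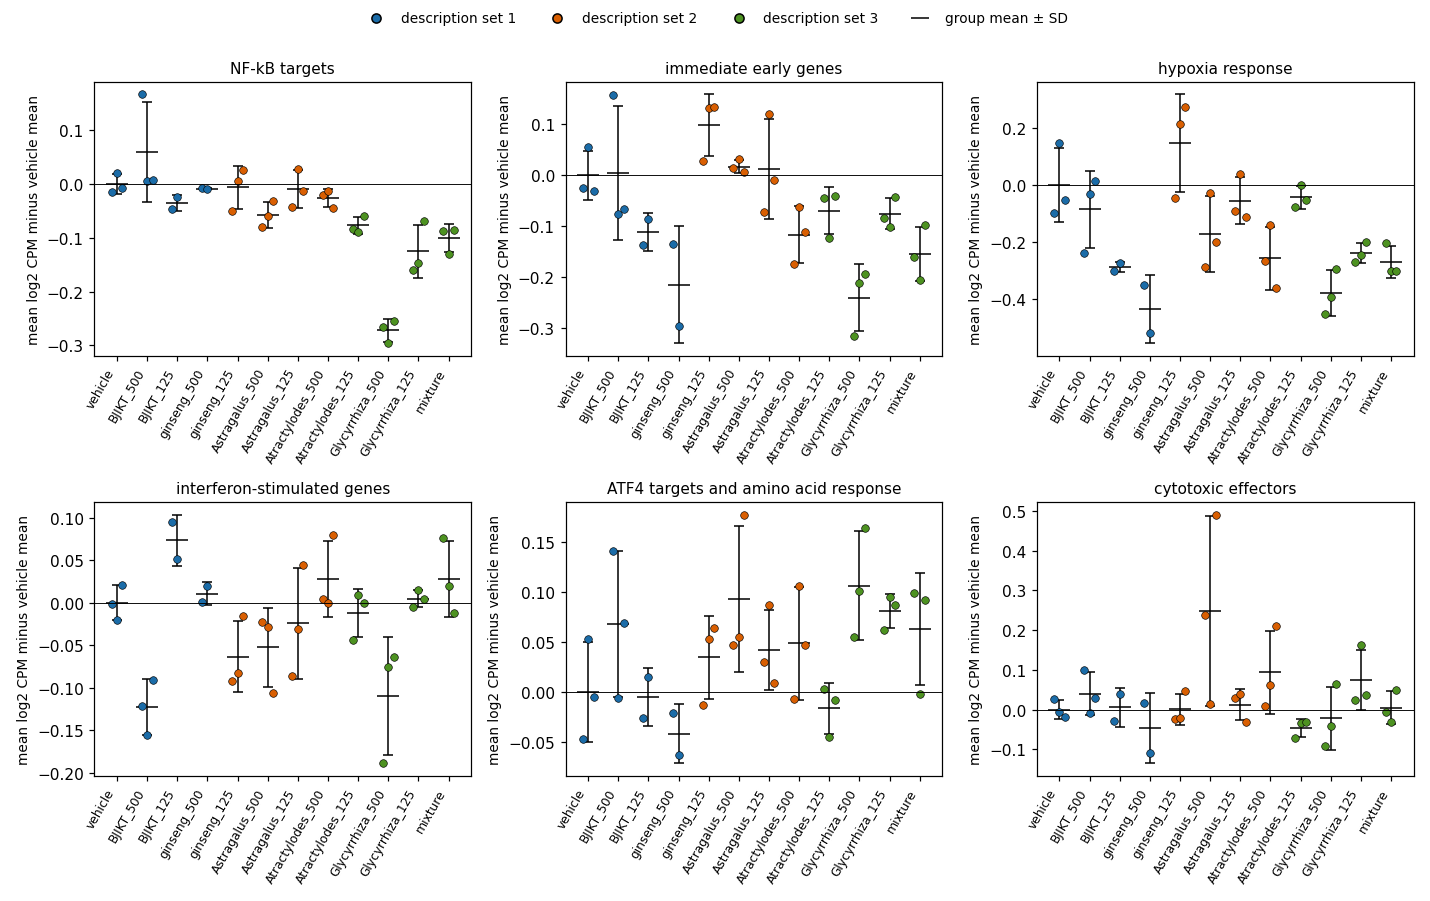
Mean log2 CPM of 6 gene lists in each library minus the mean of the vehicle libraries, coloured by description set. Hypoxia response genes lie low in ginseng_500, where their median log2 change against vehicle is -0.495, and NF-kB targets in Glycyrrhiza_500, where it is -0.247.

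BJIKT_500, the whole formula, gave no gene past the threshold against vehicle by edgeR (0, with 1446 at an unadjusted p under 0.05) and 7 by DESeq2. The 5 tested liver X receptor targets were higher as a list (median 0.173, adjusted p = 0.000106; 0.00777 with an estimated correlation; 0 past over all genes and 2 adjusted over the list alone), with ABCG1, a cholesterol exporter, at 0.36 ± 0.08 (SE, adjusted p = 0.237) and SREBF1 at 0.54 ± 0.13 (0.53). The 5 tested myeloid markers had a median of 0.158 there, with 0 past over all genes and 0 adjusted over the list alone (camera adjusted p = 0.124, 0.0268 without the atypical libraries; adjusted p = 0.308 with an estimated correlation). Heat shock genes were lower (median -0.104, 0.0433 with an estimated correlation; 0 past over all genes and 3 adjusted over the list alone), with HSPA1B at -0.78 ± 0.20 (adjusted p = 0.532). GZMB had 0.00 ± 0.12, PRF1 0.18 ± 0.09 and IFNG -0.08 ± 0.10 (adjusted p = 0.997, 0.549 and 0.853). Over the alternatives SREBF1 ran from 0.24 to 0.7 and PRF1 from 0 to 0.29. IGF1 stood at 171.8 ± 28.2 CPM (SD, n = 3). The count was 5 without BJIKT_500 replicate 2 and 4 without the 5 atypical libraries, of which BJIKT_500 replicate 1 is 1. At 125 the count was 0 (246 at an unadjusted p under 0.05), with 1 by DESeq2. Hypoxia response genes were lower there as a list (median -0.274, camera adjusted p = 0.00687 with an estimated correlation). Of them 0 passed over all genes and 1 adjusted over the list alone, with PFKFB4 at -0.73 ± 0.23 (adjusted p = 1). Glucocorticoid targets were lower too (median -0.257, camera adjusted p = 0.00162 with an estimated correlation), with 0 of 8 past over all genes and 0 adjusted over the list alone. By fry the hypoxia list missed the threshold (adjusted p = 0.126) and the glucocorticoid list passed (0.0408).

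Between the BJIKT concentrations, in 1 set, 0 genes passed by edgeR (1330 at an unadjusted p under 0.05), 5 by DESeq2 and 2 without BJIKT_500 replicate 1. Interferon-stimulated genes were lower at 500 as a list (median -0.144, adjusted p = 1.09e-11; 0.00869 with an estimated correlation), with 0 of 46 past over all genes and 9 adjusted over the list alone. IFI44 had -0.41 ± 0.09 and IFI44L -0.63 ± 0.15 (SE, adjusted p = 0.574 and 0.606). Against vehicle the list had a median of 0.069 in BJIKT_125 (camera adjusted p = 0.178 with an estimated correlation) and -0.091 in BJIKT_500 (0.0638). The difference between concentrations thus joins a higher estimate at 125 and a lower estimate at 500. Set against ginseng_500 in the same set, BJIKT_500 differed in 0 genes by edgeR (747 at an unadjusted p under 0.05), in 8 by DESeq2 and in 1 without BJIKT_500 replicate 1. Hypoxia response genes were higher as a list in BJIKT_500 (median 0.412, 0.0207 with an estimated correlation; 0 past over all genes and 8 adjusted over the list alone), with BNIP3L at 0.67 ± 0.14 (adjusted p = 0.222).

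Whether the 4 ingredients at 500 differed at all was asked with a joint test, in which 3668 genes passed by edgeR. These 4 groups lie in 3 description sets, so the count includes any difference between sets. The count was 2123 and 643 without ginseng replicates 1 and 2, 2005, 7914 and 1149 without Astragalus replicates 1, 2 and 3, 1616 and 1772 without Glycyrrhiza replicates 1 and 2, 30 with the compared groups alone and 1761 without the 5 atypical libraries. Across genes, which are not independent replicates, the changes from 125 to 500 were compared between pairs of extracts with no library in common (3 relations, exact permutation of the concentrations, two-sided). BJIKT and Glycyrrhiza had r = 0.155 (rho 0.161, p = 0.09, adjusted 0.27), Astragalus and Glycyrrhiza r = -0.272 (rho -0.338, p = 0.19, adjusted 0.285), and BJIKT and Astragalus r = -0.08 (rho -0.05, p = 0.49, adjusted 0.49). Without Glycyrrhiza_500 replicate 3 the first was 0.179 (exact permutation p = 0.04), and without the 5 atypical libraries the values were 0.048, -0.019 and 0.026. Without Glycyrrhiza_125 replicate 2 the second was -0.06, and without BJIKT_125 replicate 2 the third was 0.043. The changes of the mixture and BJIKT_500 against the same vehicle had r = 0.435 (covariance 0.0346). In 100 simulations of unchanged groups and controls, from the vehicle means, the mean r was 0.499 (0.465 to 0.545) and the covariance up to 0.0352. These drew on dispersions estimated from all 34 libraries, the atypical ones included. The vehicle replicates differed less, with a chi-square per degree of freedom of 3 to 5.65, against up to 184.33 within other groups. The simulations therefore cannot tell whether the 2 changes share more than the vehicle.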

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

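Except the covariation of the ginseng genes, their level in other groups and the counts over other splits of the samples, the tests in this part were chosen after the result was seen.

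The change from 125 to 500 µg/mL was compared between extracts with an interaction test by edgeR, for 10 pairs of extracts. BJIKT and ginseng differed in 17 genes, among them JUN, BNIP3L and PFKFB4. Ginseng and Astragalus differed in 4 genes, BNIP3L, TMEM71, DUSP1 and PTAFR. Ginseng and Glycyrrhiza differed in 1 gene, GLDC, a glycine-degrading enzyme, Astragalus and Atractylodes in 1, SHROOM2, and Atractylodes and Glycyrrhiza in 2, NFKBIA and GLDC. These genes are named after their values were seen. Without the 5 atypical libraries the 5 counts were 116, 5, 82, 31 and 823. For ginseng and Atractylodes the 2 concentrations lie in different description sets, so these differences include any difference between sets. The other 5 pairs gave 0 genes: BJIKT with Astragalus (4307 at an unadjusted p under 0.05), BJIKT with Atractylodes (2331), BJIKT with Glycyrrhiza (683), ginseng with Atractylodes (1299) and Astragalus with Glycyrrhiza (5632). Without the 5 atypical libraries these gave 0, 619, 2, 15 and 1. DESeq2 was not run for these pairs.

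In Astragalus_500, 5178 genes differed from vehicle, and the 3 libraries stood far apart. A smooth trend with transcript length and GC content as the whole cause is argued against, because 4311 genes passed with it taken out. The length used was that of the longest annotated transcript of a gene, so a trend with the length of the transcripts expressed is not covered. A profile of single libraries that also occurs in other treatments is a candidate explanation: the deviations of Astragalus_500 replicates 1 and 3 correlated with those of Atractylodes_500 replicate 3 and Glycyrrhiza_125 replicate 2 at r = 0.71 or more across genes (highest 0.91). These libraries were picked for wide deviations, which ran along transcript length in each (Spearman's rho -0.72 to -0.68). That trend was left in, so the correlations cannot tell a separate profile from it. The extract itself stays open, since the deviation of replicate 2 had r = 0.18 with the mean of the others, below the 0.3 set as the bound, and 1 library cannot exclude an effect. What made the profile cannot be told apart from these files.

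In Glycyrrhiza_500, 156 genes fell against vehicle, which lies in another description set. A difference between sets as the whole cause is argued against, unless the Atractylodes extract offsets it. Across the sets, Atractylodes_125 against the same vehicle gave a median of -0.008 for these genes. The mixture minus Atractylodes_125, both of set 3, where a set difference cancels, and neither in the comparison of Glycyrrhiza_500 with vehicle, gave -0.316 (152 of 156 lower). The highest size in another arrangement of the 6 libraries, the mirror aside, was 0.127. With 20 arrangements the real one and its mirror are 2 of 20. No arrangement test in this paragraph can therefore give a share under 0.05. Transcript length and GC content are argued against as well, since the median was -0.504 before and -0.5 after they were taken out, with 147 of the 156 genes still past. A lowering by the Glycyrrhiza extract may account for the pattern. Glycyrrhiza_125 minus Atractylodes_125, with the same Atractylodes_125 libraries, gave a median of -0.293 (highest other 0.131). Without Glycyrrhiza_125 replicate 2, which is atypical, the median was -0.262 (highest other 0.189). These genes were also lower in Astragalus_500 than in Astragalus_125 (133 of 156, median -0.25, highest other 0.15), so the pattern is not particular to Glycyrrhiza, and the reading stays a hypothesis. Of the 156, 18 were also lower in ginseng_500 than in ginseng_125, where variation between libraries is a candidate explanation too.

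In ginseng_500, 31 genes were lower than in ginseng_125, which lies in another set (median -0.848), and 13 and 0 passed without ginseng_500 replicates 1 and 2. A difference between sets as the whole cause is argued against, unless the other extracts offset it: over the libraries without ginseng, the median of these genes in set 2 minus set 1 was 0.004 (9 against 8 libraries, from -0.319 to 0.356 over 9 pairs of groups). Variation between libraries that is not tied to treatment is a candidate explanation. Within the other 10 groups, the atypical libraries included, these genes had a mean pairwise correlation of 0.327, above the highest of 1000 random sets (0.156). Those sets were matched on mean expression alone, and genes regulated together would exceed them with or without an effect of ginseng. The test therefore cannot tell such variation from an effect of the extract. The ginseng extract stays open: 2 libraries of other groups lay as low as the higher ginseng_500 library, which met the bound against it set before the result was seen. Both were of Glycyrrhiza_500 and 0 of vehicle or ginseng_125, and a low level under another extract cannot exclude an effect of ginseng, so that bound was judged wrong after the value was seen, and 2 libraries of ginseng_500 are too few to decide.

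For groups of 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave the highest count, 1 of 10, for Glycyrrhiza_500 (224, highest other 0), Glycyrrhiza_125 (21, 0), the mixture (52, 0), the Glycyrrhiza concentrations (6, 0), the mixture against Atractylodes_125 (55, 0), the mixture against BJIKT_500 (27, 0) and Astragalus_500 against vehicle (5178, 3926). For the Astragalus concentrations 3 of 10 splits gave as many as 4181 (highest other 4444), and for Astragalus_500 against Atractylodes_500 2 of 10 gave as many as 212, with 6553 in a split that put Astragalus_500 replicates 1 and 3 with Atractylodes_500 replicate 3, which points to a structure of the samples. Where the real count was 0 (BJIKT_500, ginseng_125, Astragalus_125, Atractylodes_500 and Atractylodes_125 against vehicle, the Atractylodes concentrations, and the mixture against Glycyrrhiza_125), every split gives as many whatever the data, so 10 of 10 (highest other 0) says nothing of chance. The same holds for 100 of 100 drawn splits for the mixture against the sum of its parts, with a real count of 0 and a highest other of 0.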

How the results depend on the processing

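The fits without the 5 atypical libraries and with length and GC offsets were chosen after seeing the data; the others were fixed beforehand. Comparisons are written by their groups, "against vehicle" where 1 group is given, and values are counts of genes past the threshold unless said otherwise. With RLE factors each of the 23 counts stayed within 1.5 times the value reported, and with the replicate number as a block each but that between the Glycyrrhiza concentrations (1). The cause of the shifts below was not tested, except that leaving out libraries leaves fewer samples. Depth limits what can be said of genes with low counts, which the filter removed. Every correlation of 2 concentrations kept its side of the threshold, except as given last.

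With no filter the counts were 330 for BJIKT_500, 36 for BJIKT_125, 92 for ginseng_500, 52 for ginseng_125, 95 for Astragalus_125, 884 for Atractylodes_500, 194 for Atractylodes_125, 297 for Glycyrrhiza_125 and 206 for the mixture. They were 235, 119, 1792 and 94 between the concentrations of BJIKT, ginseng, Atractylodes and Glycyrrhiza. The mixture gave 470 against BJIKT_500, 143 against Glycyrrhiza_125, 173 against Atractylodes_125 and 60 against the sum of its parts, Astragalus_500 1366 against Atractylodes_500, and BJIKT_500 147 against ginseng_500.

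DESeq2 gave 7 for BJIKT_500, 1 for BJIKT_125, 22 for ginseng_500, 2 for ginseng_125, 4 for Astragalus_125, 39 for Atractylodes_500, 3 for Atractylodes_125, 362 for Glycyrrhiza_500, 75 for Glycyrrhiza_125 and 122 for the mixture. It gave 5, 57, 105 and 35 between the concentrations of BJIKT, ginseng, Atractylodes and Glycyrrhiza. The mixture gave 356 against BJIKT_500, 2 against Glycyrrhiza_125, 132 against Atractylodes_125 and 3 against the sum of its parts, Astragalus_500 430 against Atractylodes_500, and BJIKT_500 8 against ginseng_500.

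With the compared groups alone the counts were 65 for ginseng_500, 46 for ginseng_125, 0 for Astragalus_500, 3 for Astragalus_125, 4 for Atractylodes_500, 810 for Atractylodes_125, 737 for Glycyrrhiza_500, 66 for Glycyrrhiza_125 and 369 for the mixture. They were 66, 0, 1397 and 1 between the concentrations of ginseng, Astragalus, Atractylodes and Glycyrrhiza, 0 and 726 for the mixture against BJIKT_500 and Atractylodes_125, 0 for Astragalus_500 against Atractylodes_500 and 30 among the 4 ingredients.

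Without the 5 atypical libraries the counts were 4 for BJIKT_500, 47 for ginseng_500, 143 for Astragalus_500, 13 for Astragalus_125, 719 for Atractylodes_500, 1 for Atractylodes_125, 1174 for Glycyrrhiza_500, 154 for Glycyrrhiza_125 and 577 for the mixture. They were 3, 168, 23, 2248 and 37 between the concentrations of BJIKT, ginseng, Astragalus, Atractylodes and Glycyrrhiza, 193 and 717 for the mixture against BJIKT_500 and Atractylodes_125, 11 for BJIKT_500 against ginseng_500 and 1761 among the 4 ingredients. With length and GC offsets they were 1 for BJIKT_500, 12 for ginseng_500, 1 for Astragalus_125, 1 for Atractylodes_125, 565 for Glycyrrhiza_500, 113 for Glycyrrhiza_125, 166 for the mixture, 63, 1 and 28 between the concentrations of ginseng, Atractylodes and Glycyrrhiza, 166 for the mixture against Atractylodes_125 and 635 for Astragalus_500 against Atractylodes_500.

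Leaving out each library in turn gave 0 to 5 for BJIKT_500, 0 to 6 for ginseng_500, 419 to 8221 for Astragalus_500, 0 to 1 for Atractylodes_500, 134 to 157 for Glycyrrhiza_500, 4 to 9 for Glycyrrhiza_125 and 8 to 22 for the mixture. Between concentrations it gave 0 to 2 for BJIKT, 0 to 39 for ginseng, 19 to 7883 for Astragalus and 0 to 2 for Glycyrrhiza. The mixture gave 1 to 643 against BJIKT_500 and 23 to 30 against Atractylodes_125, Astragalus_500 94 to 5218 against Atractylodes_500, BJIKT_500 0 to 1 against ginseng_500, and the 4 ingredients 643 to 7914. For the other 7 comparisons, each with a count of 0, it gave 0.

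The 106 list calls became 19 with an estimated correlation. The correlation of the mixture with BJIKT_500 was 0.312 with a CPM of at least 10, 0.348 without the 5 atypical libraries and 0.342 to 0.52 with 1 library left out. With 1 library left out, the correlation of Astragalus with Glycyrrhiza ranged from -0.362 to -0.06 (-0.516 with a CPM of at least 10), that of BJIKT with Astragalus from -0.174 to 0.043, and that of BJIKT with Glycyrrhiza from 0.076 to 0.185 (0.314 with a CPM of at least 10, -0.12 for BJIKT with Astragalus). The last passed without Glycyrrhiza_500 replicate 3 (0.179). Of 192 named gene results 156 were past the threshold, and in 2 of these the sign turned, both in Astragalus_500: NCR3 against vehicle was -0.15 without the 5 atypical libraries and -0.03 with length and GC offsets, and GNLY against Astragalus_125 was -0.01 without the 5 atypical libraries. Of the 36 not past it, the sign turned in 8 under at least 1 setting, for example IFNG in BJIKT_500 and GNLY in Glycyrrhiza_500. Of the 156, 80 passed under each setting fixed beforehand other than leaving out a library, 83 lost the call in at least 1 fit with a library left out and 16 without the atypical libraries.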

Other observations

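The test of Glycyrrhiza and that of BJIKT as accounts of the mixture's genes were chosen after the result was seen.

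Genes that fell in Glycyrrhiza_500 against vehicle were compared with other comparisons that share no library with it. Of the 31 genes lower in ginseng_500 than in ginseng_125, 18 also fell in Glycyrrhiza_500, where independent lists would share 0.3, and of those lower in Astragalus_500 than in Astragalus_125, 81, where 18 would be shared. Genes are not independent, so these expected counts are a reference and no test. Of the 68 genes that rose, 67 were higher in the mixture than in Atractylodes_125, with a median of 0.164.

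A hypothesis is that Glycyrrhiza, at the concentration it has in the mixture, accounts for much of what the mixture changed. The 52 genes of the mixture had a median change of 0.48 in its direction. In Glycyrrhiza_125 minus Atractylodes_125, which shares no library with that comparison, their median was 0.319 (52 of 52 in the same direction, highest other arrangement 0.132). Glycyrrhiza may thus account for most of it, though 20 arrangements are too few for a share under 0.05. Astragalus_125 against vehicle gave 0.218 (52 of 52) and ginseng_125 -0.032 (16 of 52), but these share the vehicle libraries with the mixture's own change. That the whole formula at 500 changes these genes more than at 125 is argued against by a median of -0.018 in BJIKT_500 minus BJIKT_125 (25 of 52, highest other 0.087). A change alike at both concentrations would cancel there, and against the shared vehicle the median was 0.088 for BJIKT_500 (41 of 52) and 0.111 for BJIKT_125 (47 of 52).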
